A study of Mus musculus with 8 samples.

How the data were processed

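Transfer RNA-derived fragments (tRFs) were measured by small RNA sequencing in 8 libraries of dissociated C57BL/6NRj mouse islet cells, 4 untreated and 4 exposed to a cytokine mix. Per the labels' protocols, RNA was extracted with a miRNeasy kit and pretreated with an rtStar kit made for tRFs, and libraries were made with the QIAseq miRNA kit. Pretreatments of this type remove end groups and base methylations that hinder library construction, so levels depend on how completely they work. The QIAseq kit adds molecular identifiers, and the sources used here do not say whether they were collapsed. Per the submitters' processing notes, Bowtie 1 and the GRCm38.p6 build were used. Per the file headers, reads were counted per distinct fragment sequence, each sequence was assigned to every tRNA gene it matches, and edgeR and DESeq were run by the authors; the versions are not given in the sources used here.

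The deposited tables hold raw read counts per tRF and library, not normalized. Per the file headers they also hold 2 kinds of TPM, but read count divided by TPM was the same number in all 8 libraries (constants of 13345182 and 873510 reads, from 835 values each), so these deposited TPM values are not normalized between libraries and were not used for comparisons. The authors' log2 fold changes and mean log2 CPM come from edgeR and further log2 fold changes with standard errors from DESeq, per the file headers. The authors' p-values, FDR and adjusted p-values and the DESeq test statistic (a score) were read from the same tables, as was the deposited DESeq base mean. The tables hold only tRFs past the authors' listing, 29 up and 83 down, with FDR under 0.05. FDR multiplied by rank and divided by p gave 31661 tested tRFs at all 85 ranks where it can be read, so the list is complete for its threshold and the tRFs outside it were not analysed here. A selection of this kind favours chance differences in the same direction, so fold changes of listed tRFs tend to be too large, most for those with few reads.

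Library sizes were needed to compute CPM and were recovered from the authors' values. The 8 sizes and 1 dispersion that return the authors' mean log2 CPM were fitted by least squares with edgeR's average log CPM function (prior count 2). The fit returned those values within 5e-07 and a dispersion of 0.246. The edgeR fit with these sizes returned the authors' log2 fold changes with a median absolute difference of 0.00218 and a largest of 0.0737, under the limit of 0.1 set for the median. These are effective sizes and may include the authors' scaling factors. On simulated data (3 runs) they were recovered within 9.7e-05%. The authors' DESeq size factors were likewise read from their base means by linear regression (largest error 3.4e-13) and served as an alternative added after seeing the data.

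The counts of all 112 listed tRFs were tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) with treatment as the only term and no further scaling factor, because tRFs listed for having changed cannot supply an unchanged majority. P-values were adjusted by Benjamini-Hochberg over the listed tRFs, with a threshold of 0.05. SE is the log2 fold change divided by the square root of the F statistic. The common dispersion was 0.162, a biological coefficient of variation of 0.402. On simulated counts with these means and sizes (20 runs of 112 tRFs, 40 changed in each), the test called 81.2% of tRFs changed 4-fold, 27.5% of those changed 2-fold and 0.625% of unchanged ones, with 0 called in the wrong direction. Every simulated tRF had the common dispersion of tRFs that were listed for differing, so these rates may be too favourable. They also leave out the authors' choice of the list from all tested tRFs. Sums of CPM over the listed tRFs of a group (fragment class, origin, isotype, anticodon or length, with at least 5 listed tRFs) were compared on the log2 scale by an exact two-sided permutation test over 70 assignments, adjusted over 19 groups. Group membership was set against direction by Fisher's exact test, adjusted over 23 groups. The isotype and anticodon groups of His and of Cys hold the same tRFs, and the mitochondrial group had too few tRFs for a test. Where a group held 1 to 3 reads of a named tRF, the ratio of pooled reads was given with an exact 95% interval (Clopper-Pearson, conditional on the total), a choice made after seeing the data. A fold against a group with 0 reads was computed from pooled reads against a floor of 3 reads over the group.

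The design, the rule for named tRFs and the alternatives were fixed before the data were examined, except where stated. In each direction the rule took the 8 tRFs with the largest absolute log2 fold change among those past the threshold whose groups did not overlap in CPM, and the 5 with the highest mean CPM among those past the threshold, with at most 2 tRFs per isoacceptor in each part, a fragment of several isoacceptors counting under each. It gave 12 tRFs listed up and 13 listed down. Names give the isodecoders and the first and last position as the deposited tables count them. Position 0 is the base before position 1, and the tRNA-His fragments that start there have C or T at it. Alternatives were the listed totals as library sizes, TMM factors (edgeR) and DESeq2 size factors over the listed tRFs, the DESeq2 Wald test, limma on log2(CPM + 1), edgeR's exact test, a filter of 10 reads in 4 libraries, a 2-fold and unadjusted p threshold, the replicate number as a block, each library left out, and counting each set of parent tRNAs and fragment class once in each direction. To look for a library deposited more than once, libraries of a group were compared in pairs by chi-square tests (chi-square per degree of freedom 2.51 to 18.6), and none was counted as a copy. These tests cover counting error only and do not show that the libraries are independent replicates.

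Nuclear loci were taken from RefSeq genes of GRCm38.p6 where both the deposited tables and RefSeq have 1 tRNA gene of that anticodon on the chromosome. Overlap with genes was read from GENCODE M21, and mitochondrial fragments were matched exactly to its transcripts. Analyses used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.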

Results

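Small RNA sequencing was used to measure tRNA-derived fragments (tRFs), short RNAs cleaved from transfer RNAs, in dissociated cells of mouse islets of Langerhans, the hormone-secreting clusters of the pancreas whose beta cells make insulin. Cells of 12-week-old C57BL/6NRj mice were left untreated or were exposed for 24 h to 3 pro-inflammatory cytokines, 0.1 ng/mL IL-1β, 10 ng/mL TNF-α and 30 ng/mL IFN-γ. The comparison asked how cytokines of the kind released by immune cells that invade the islet in type 1 diabetes affect the tRF content of islet cells. Each group held 4 libraries. Nothing in the labels says that these came from separate animals or cultures, so the p-values measure the spread between the libraries, which may be technical. The effective library sizes behind the authors' values were 666240, 791366, 372260 and 659827 reads in control replicates 1 to 4 and 367453, 464770, 570383 and 939109 reads in cytokine replicates 1 to 4. The listed tRFs took 9299, 9944, 4904 and 11577 reads of the control libraries and 2659, 2743, 6618 and 11107 reads of the cytokine libraries. At these depths, the level that 3 reads stand for lay between 3.20 and 8.16 CPM per library (CPM, read count scaled by the effective library size). Such floors cover counting error only.

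In cytokine-treated cells internal fragments of tRNA-His-GTG with starts at position 17 or later and internal fragments of tRNA-Pro ending at position 52 were higher. Fragments that run to the CCA tail of tRNA-Arg were lower, except that 6 of 47 and 12 of 47 of these had fold changes above 0 with TMM factors and with DESeq2 size factors computed over the listed tRFs. With those factors only 2 of the 47 and 0 of the 47 passed as lower (edgeR). Such factors set the typical listed tRF to no change, and most were listed down, so this loss of calls cannot tell whether the fragments fell. The authors' deposited tables listed 29 tRFs as higher and 83 as lower in cytokine-treated cells, out of 31661 tRFs that their false discovery rates (FDR) imply were tested. In the authors' deposited tables the log2 fold changes ran from 1.80 to 5.65 for tRFs listed up (median 3.11). Those listed down ran from -5.84 to -1.48 (median -2.61) in the authors' deposited tables, and the largest FDR was 0.0489. The tRFs listed up comprised 28 internal fragments (i-tRFs) and 1 fragment from the 5′ end (5-tRF). Those listed down comprised 39 fragments from the 3′ end (3-tRFs), 26 internal fragments, 11 long 3′ fragments cleaved near the anticodon (3-tRHs), 5 5-tRFs and 2 long 5′ fragments cleaved near the anticodon (5-tRHs). Per the authors' deposited tables, their DESeq test had an adjusted p under 0.05 for 27 of the 29 and 75 of the 83, gave no adjusted p for 1 listed up, and had the same direction for all 112. Every tRF examined here was listed because it differed between these same libraries. Tests on them give errors and an order within the list and are not independent evidence of a change.

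**Figure D1:**
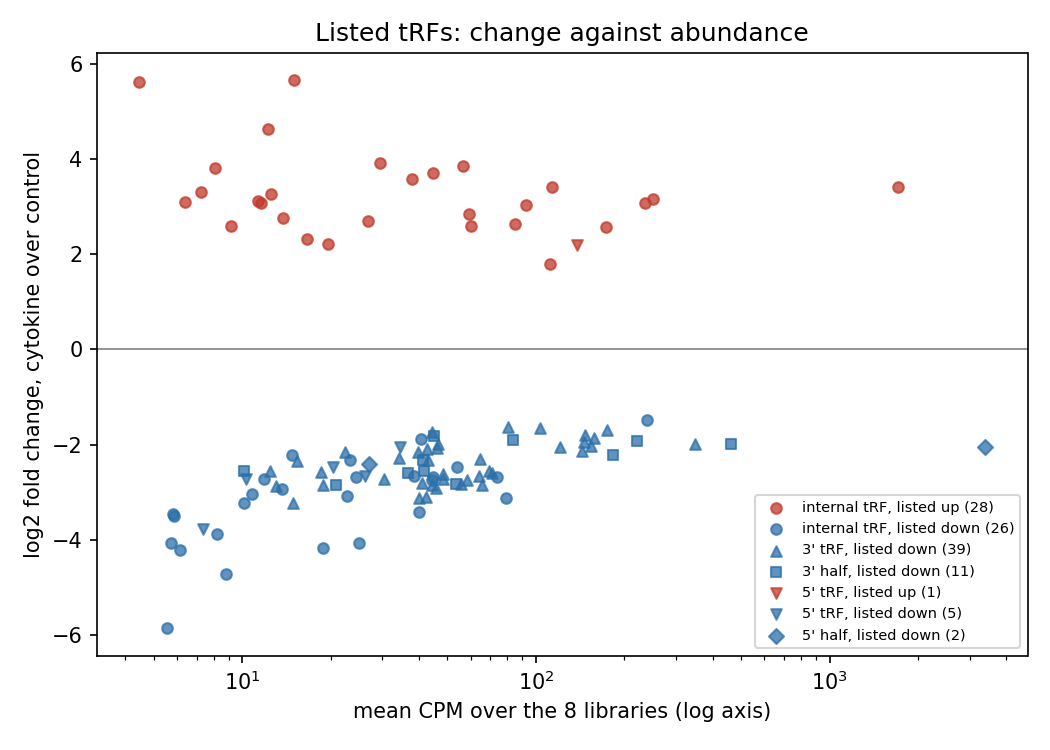
Each point is 1 of the 112 listed tRFs, placed by its mean CPM over the 8 libraries (log axis) and its log2 fold change of cytokine over control (edgeR), with the fragment class as marker shape and the authors' list as colour. The fitted values run from 1.80 to 5.66 for tRFs listed up and from -5.86 to -1.48 for those listed down, and with TMM and DESeq2 factors 8 and 15 of the latter are above 0; the value of -5.86 is for a tRF with 0 cytokine reads, at least 9.72-fold lower.

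Among the tRFs that rose, the most abundant by far was the fragment of positions 21 to 53 of tRNA-His-GTG-2 and tRNA-His-GTG-3 (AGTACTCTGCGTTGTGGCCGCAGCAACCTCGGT, matching 9 tRNA genes). Its level was 292 ± 170 CPM in controls and 3125 ± 1443 CPM with cytokines (SD, n = 4 per group), a log2 fold change of 3.42 ± 0.49 (SE). Its neighbours behaved alike, with log2 fold changes of 3.40 ± 0.47 (SE) for positions 21 to 52 and 3.15 ± 0.46 (SE) for positions 20 to 53. Internal fragments of tRNA-Pro that ended at position 52 also rose. Positions 18 to 52 went from 50.2 ± 23.4 to 421 ± 252 CPM in Pro-TGG-2, a log2 fold change of 3.08 ± 0.49 (SE). The levels were 49.8 ± 31.4 and 297 ± 163 CPM in Pro-CGG-1 and 6.48 ± 3.96 and 82.8 ± 44.9 CPM in Pro-TGG-1 (SD, n = 4 per group), with log2 fold changes of 2.57 and 3.72. The Pro-TGG-1 fragment matched a single gene (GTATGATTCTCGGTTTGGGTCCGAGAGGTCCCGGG), and positions 19 to 52 of the same tRNA rose by 3.58 ± 0.63 (SE). The only 5′ fragment listed up, positions 1 to 38 of Pro-TGG-2, went from 49.1 ± 19.5 to 226 ± 158 CPM (SD, n = 4 per group), a log2 fold change of 2.19 that was 1.58 without cytokine replicate 3, in which the level was 461 CPM.

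Fragments of tRNA-Lys-TTT-1 that were near absent from controls rose too. Positions 21 to 70 gave 1 read over the 4 control libraries and stood at 29.8 ± 17.4 CPM with cytokines (SD, n = 4). The log2 fold change was 5.66 ± 0.85 (SE). Without control replicate 1, which held that read, the controls had 0 reads and the level was at least 19.7-fold higher (floor of 3 reads over the group). The ratio of pooled reads, 76 against 1, was 80.8 after scaling to library size (exact 95% interval 14.1 to 3233, counting error only). Positions 21 to 71 had 0 reads in the controls and 26 reads with cytokines, at least 9.21-fold higher when the floor is 3 reads over the group. Cytokine replicate 4 held most of those reads, and without it the bound was 4.73-fold. Fragments of tRNA-Arg that stopped at position 73, the last base before the CCA tail, rose as well. Positions 42 to 73 went from 4.19 ± 4.75 to 54.9 ± 22.1 CPM in Arg-CCG-2 (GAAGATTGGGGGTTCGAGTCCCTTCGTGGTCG) and from 8.27 ± 8.87 to 105 ± 48.9 CPM in the sequence shared by Arg-CCG-1 and Arg-TCG-2 (SD, n = 4 per group), with log2 fold changes of 3.92 ± 0.66 and 3.86 ± 0.58 (SE). Without control replicate 3 these were 4.70 and 4.73.

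Among the tRFs that fell, the most abundant was a 5-tRH of positions 1 to 31 shared by Pro-AGG-1, Pro-CGG-1 and Pro-TGG-2 (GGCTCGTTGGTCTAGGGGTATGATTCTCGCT, matching 13 tRNA genes). It went from 5453 ± 1888 CPM in controls to 1318 ± 231 CPM with cytokines (SD, n = 4 per group), a log2 fold change of -2.05 ± 0.43 (SE). With TMM and DESeq2 size factors over the listed tRFs this was -0.21 and -0.12, and neither passed (edgeR). Fragments of tRNA-Arg that ended in the full CCA tail made up 47 of the 83 tRFs listed down. They began anywhere from position 28 to position 61 and had log2 fold changes from -3.22 to -1.62 (edgeR). The most abundant of them, positions 35 to 76 of Arg-TCG-3, went from 736 ± 307 to 185 ± 47.4 CPM, and positions 28 to 76 of the same tRNA went from 554 ± 361 to 139 ± 28.9 CPM (SD, n = 4 per group). Positions 35 to 76 of Arg-ACG-3 had a log2 fold change of -1.91 ± 0.43 (SE). A short internal fragment of tRNA-Cys, positions 34 to 53 of Cys-GCA-3, Cys-GCA-7 and Cys-GCA-8, went from 352 ± 79.5 to 126 ± 21.4 CPM (SD, n = 4 per group), a log2 fold change of -1.48 ± 0.37 (SE). With the listed reads as library sizes, this Cys fragment no longer passed (log2 fold change -0.74, adjusted p = 0.0675, edgeR).

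Rare internal and 5′ fragments had few or no reads with cytokines. Positions 16 to 55 of Thr-TGT-2 and Thr-TGT-3 had 31 reads in the controls and 0 with cytokines, at least 9.72-fold lower with a floor of 3 reads over the group. Positions 1 to 55 of Thr-TGT-2 had a log2 fold change of -3.77 ± 0.73 (SE) and positions 16 to 54 of Lys-CTT-3 one of -3.87 ± 0.77 (SE). Internal fragments of tRNA-Arg that ended at position 54 or 55 fell with their CCA-ending relatives, by log2 fold changes of -4.73 ± 0.96 (Arg-TCG-4, 15 to 54), -4.21 ± 0.84 (3 Arg-TCG isodecoders, 28 to 55), -4.17 ± 0.75 (Arg-CCG-1, 34 to 54) and -4.07 ± 0.64 (Arg-CCG-2, 35 to 54), each with its SE. Positions 4 to 30 of His-GTG-2 had a log2 fold change of -4.07 ± 0.88 (SE), from 11.2 ± 7.24 to 0.266 ± 0.532 CPM (SD, n = 4 per group). With 1 or 2 reads in the cytokine group, the pooled ratios of control over cytokine were 35.7 for Arg-TCG-4 (exact 95% interval 6.04 to 1448), 27.3 for the 28 to 55 fragment (4.52 to 1114), 22.6 for the His fragment (3.68 to 928), 17.4 for Lys-CTT-3 (4.49 to 149) and 16.5 for Thr-TGT-2 (4.23 to 141). Without cytokine replicate 4, which held the only cytokine read of each, Arg-TCG-4 was at least 7.14-fold and the His fragment at least 4.51-fold lower. Without cytokine replicate 2 the 28 to 55 fragment likewise was at least 7.29-fold lower, and the fitted value of Arg-CCG-1 was -4.79.

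**Figure D2:**
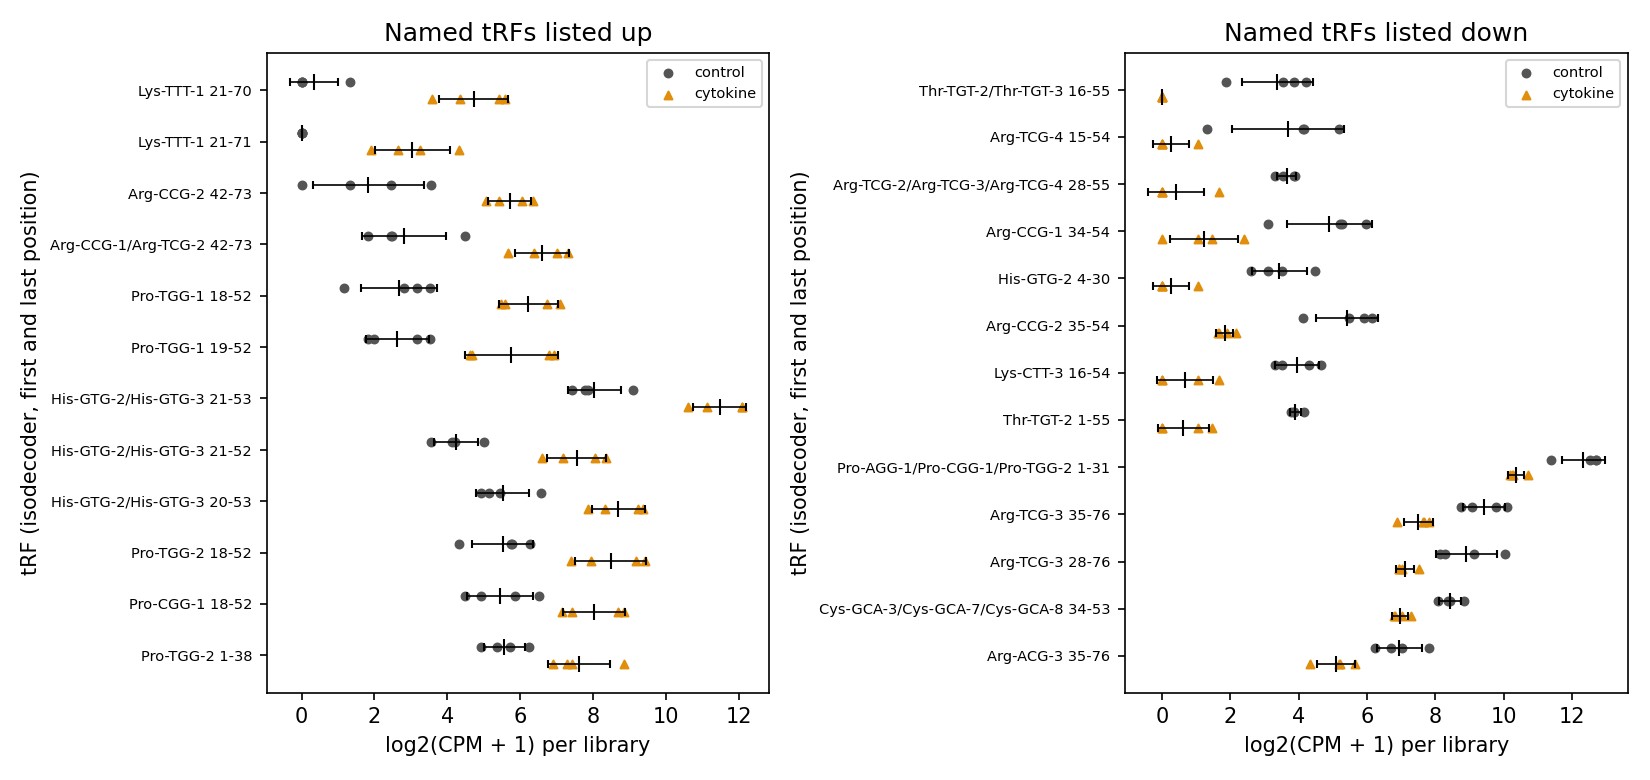
Points are the log2(CPM + 1) of each of the 4 control (circles) and 4 cytokine (triangles) libraries for the 12 tRFs named from the list of higher tRFs and the 13 named from the list of lower tRFs. Vertical marks and bars are the mean and SD of the 4 values; in all 25 the values of both groups do not overlap.

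All 112 listed tRFs passed an adjusted p of 0.05 in the edgeR quasi-likelihood test, 29 higher and 83 lower, with adjusted p from 7.34e-06 to 0.000627. In 28 of the 29 and 82 of the 83 the values of both groups did not overlap. Chance gives this for 2.86% of tRFs that were not chosen for a difference. These were listed because they differed between the same libraries, so the separation is not evidence against chance. The split of directions and the calls of tRFs listed down depended on the scaling. With TMM factors computed over the listed tRFs 29 higher and 11 lower passed, and with DESeq2 size factors computed over them 29 higher and 5 lower. These scalings moved the log2 fold changes of the listed tRFs by a median of 1.84 and 1.95. Both set the typical listed tRF to no change, and most were listed down. A loss of calls among those listed down was thus built in, and cannot tell whether they fell. With sizes from the authors' DESeq size factors all 29 and all 83 passed, with median log2 fold changes of 3.26 and -2.48. All 12 named up passed with both the TMM and the DESeq2 factors over the listed tRFs. Of the 13 named down, the 5 named for their abundance and His-GTG-2 4 to 30 did not pass with TMM factors, and with DESeq2 factors only Thr-TGT-2 and Thr-TGT-3 16 to 55, Arg-CCG-1 34 to 54 and Arg-CCG-2 35 to 54 passed. With those factors 8 and 15 of the tRFs listed down had fold changes above 0, none past the threshold, among them the Cys fragment of positions 34 to 53 (0.42 and 0.51) and, with the DESeq2 factors, Arg-TCG-3 28 to 76 (0.09), Arg-TCG-3 35 to 76 (0.04) and Arg-ACG-3 35 to 76 (0.04).

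When the listed fragments were summed by tRNA, the His-GTG sum was 487 ± 210 CPM in controls and 4074 ± 1882 CPM with cytokines (SD, n = 4 per group), 8.13-fold higher. The tRNA-Arg sum went from 6825 ± 1910 to 1663 ± 252 CPM, 4.02-fold lower, but with TMM factors the log2 difference was -0.11 and did not pass (exact permutation p = 0.257). The tRNA-Cys sum went from 723 ± 234 to 208 ± 28.6 CPM, 3.36-fold lower (SD, n = 4 per group), but was higher with TMM factors (log2 difference 0.15). By fragment class, the 3-tRF sum fell from 4533 ± 1324 to 1013 ± 154 CPM and the 3-tRH sum fell from 1942 ± 571 to 451 ± 90.7 CPM (SD, n = 4 per group). With TMM factors their log2 differences were -0.23 and -0.19 and did not pass. All 39 listed 3-tRFs and all 11 listed 3-tRHs were listed down, so a fall of both sums was built into the list. The sum of internal fragments, of which the His-GTG fragment of positions 21 to 53 alone took 292 and 3125 CPM, rose from 2120 ± 536 to 6097 ± 2667 CPM (SD, n = 4 per group). That rise did not pass without control replicate 1, 2 or 4 (adjusted p = 0.0776, exact permutation test) or 3 (adjusted p = 0.0724, exact permutation test), with log2 differences of 1.51, 1.25, 1.56 and 1.49, nor as a mean of log2(CPM + 1) over its tRFs (0.19, adjusted p = 0.509, exact permutation test). Without any 1 control the nuclear sum did not pass either (log2 difference -0.78 to -0.62), and without any 1 cytokine library the Pro-CGG sum did not (-1.78 to -1.55). The nuclear sum also failed to pass with the authors' DESeq size factors (-0.57, adjusted p = 0.0679, exact permutation test), and the Pro-CGG sum with listed totals (-0.95, adjusted p = 0.0724, exact permutation test). In the 5-tRF sum 5 fragments were listed down and 1 up, Pro-TGG-2 1 to 38, which alone took 49.1 and 226 CPM. That sum did not differ detectably (218 ± 56.2 against 255 ± 163 CPM, exact permutation test, two-sided, adjusted p = 0.943, n = 4 per group), but the mean of log2(CPM + 1) over its 6 tRFs was lower (-1.96, adjusted p = 0.0362, exact permutation test). Nor did the tRNA-Lys sum differ (54.2 ± 17.7 against 59.3 ± 25.2 CPM; adjusted p = 0.943, exact permutation test), in which 3 Lys-TTT fragments were listed up and 3 Lys-CTT fragments down. With TMM factors the 5-tRF and the Lys sum each had a log2 difference of 1.98 (exact permutation p = 0.0286, adjusted p = 0.0776). The tRNA-Pro sum, with 7 fragments up and 8 down, was 5991 ± 2014 CPM in controls and 2742 ± 940 CPM with cytokines (SD, n = 4 per group) and did not pass (adjusted p = 0.102, exact permutation test). Its log2 difference was -1.11, -1.41 without control replicate 3, where it passed (adjusted p = 0.0388, exact permutation test), and 0.78 with TMM factors. The Pro-TGG sum likewise passed only without that library among those left out (-1.59). With sizes from the authors' DESeq size factors both passed as lower, at -0.96 for Pro and -1.14 for Pro-TGG (adjusted p = 0.0362, exact permutation test). The Pro, Pro-CGG and Pro-TGG sums all hold the 5-tRH of positions 1 to 31, which went from 5453 ± 1888 to 1318 ± 231 CPM. The Pro-CGG sum was 5701 against 1750 CPM and the Pro-TGG sum 5818 against 2327 CPM. These sums were lower through that 1 fragment, since the mean CPM of the rest of each was higher with cytokines. Fragments under 25 nt fell from 1087 ± 105 to 298 ± 45.2 CPM and those of 25 to 29 nt fell from 1226 ± 452 to 259 ± 57.7 CPM (SD, n = 4 per group), and the sum of fragments of 30 nt or more was 11997 ± 2174 against 8585 ± 2974 CPM (adjusted p = 0.224, exact permutation test), a result that depended on the setting. It was higher and passed with listed totals (log2 difference 0.16, adjusted p = 0.0388, exact permutation test), was 1.36 with TMM factors without passing, and passed as lower as a mean of log2(CPM + 1) (-0.63, adjusted p = 0.0362, exact permutation test). With listed totals each sum is a share of the listed reads. The shares under 25 nt and of 25 to 29 nt then fell (log2 differences -1.18 and -1.50), so the larger share of longer fragments does not show a higher level. In all, 14 of the 19 sums passed, each at an exact two-sided p of 0.0286, the smallest that 70 assignments of 4 against 4 libraries can give, and an adjusted p of 0.0388. The summed tRFs were listed on these same libraries, so these passes are not independent evidence that a class or a tRNA changed. All 15 listed tRFs of 25 to 29 nt and 13 of the 14 under 25 nt, for example, were listed down. With TMM factors 0 of the 19 passed, and the differences of the nuclear, Arg-TCG, Pro-CGG and under 25 nt sums, which all passed as lower, were above 0. At an unadjusted p under 0.05, 7 sums passed with TMM factors, all as higher, among them the His-GTG sum (log2 difference 4.92) and the sum of internal fragments (3.35). TMM factors over the listed tRFs set the typical listed tRF to no change, and most were listed down. The values with these factors therefore cannot tell whether a sum fell.

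**Figure D3:**
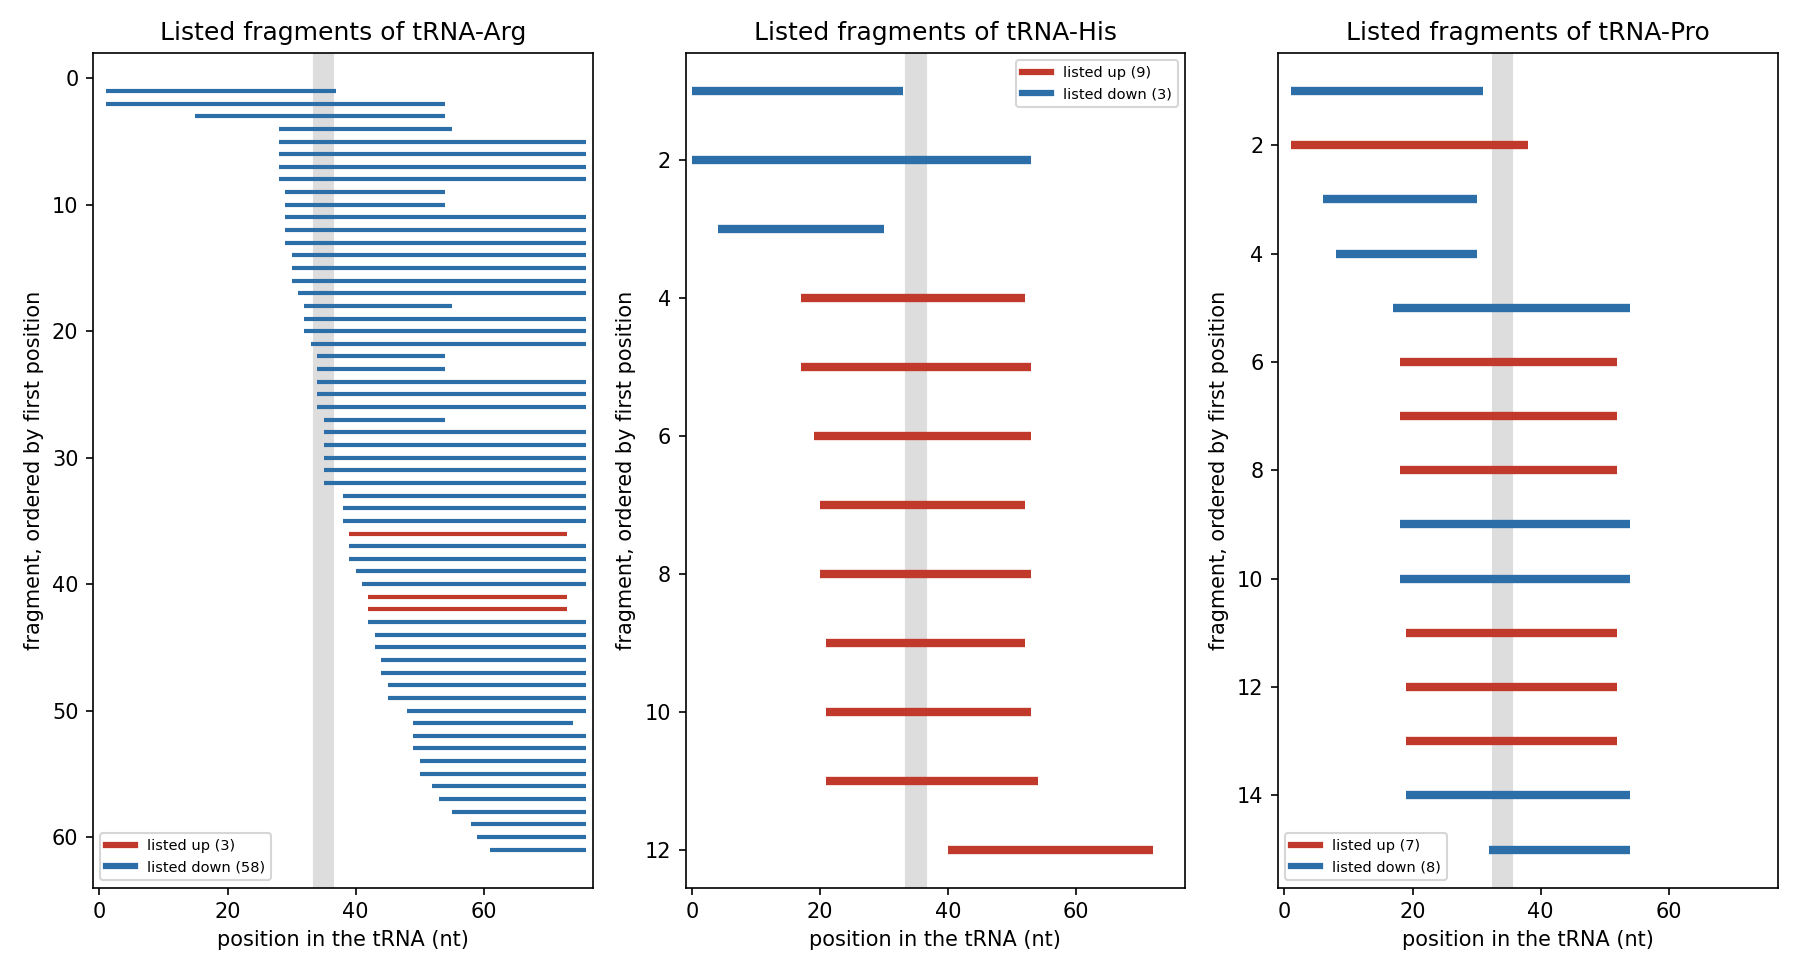
Horizontal bars run from the first to the last position of each listed fragment of tRNA-Arg (61 fragments), tRNA-His (12) and tRNA-Pro (15), coloured by the authors' list, with the anticodon shaded in grey. In tRNA-Arg the 3 fragments listed up end at position 73 and 47 of the 58 listed down run to position 76; in tRNA-His 9 internal fragments were listed up and 3 fragments with starts at positions 0 and 4 were listed down.

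Listed tRFs of some fragment classes and parent tRNAs were listed mostly in 1 direction. Internal fragments made up 28 of the 29 tRFs listed up and 26 of the 83 listed down (Fisher's exact test, two-sided, adjusted p = 5.72e-09), whereas 3-tRFs made up 0 and 39 (adjusted p = 3.79e-06, Fisher's exact test). Of the 28 internal fragments listed up, 5 ended at the last base before the CCA tail. These lack only that tail at their 3′ end but are not classed as 3-tRFs. The contrast of the classes is thus partly one of the CCA tail. Fragments of tRNA-Arg were 3 of those listed up and 58 of those listed down (adjusted p = 1.95e-07, Fisher's exact test), and fragments of tRNA-His were 9 and 3 (adjusted p = 0.00086, Fisher's exact test). In all, 10 of 23 groups passed. Because fragments of 1 tRNA overlap, each set of parent tRNAs and class was also counted once in each direction. A set with fragments in both lists, such as the internal fragments of Pro-CGG-1, Pro-TGG-2 and Arg-CCG-2, counted under both. That left 14 listed up and 34 listed down and 1 group past the threshold, internal fragments (adjusted p = 0.022, Fisher's exact test). Of the tRNA-His sets, 25% were then listed up. Of the 10 tRNAs chosen beforehand because their 5′ fragments are often abundant in mouse small RNA, 5 had a listed fragment: His-GTG with 9 up and 3 down, Lys-TTT with 3 up, Lys-CTT with 3 down, and Glu-CTC and Asp-GTC with 1 down each. Gly-GCC, Gly-CCC, Glu-TTC, Val-CAC and Val-AAC had 0 listed fragments. The 5 tRNAs had 20 listed tRFs, of which 20 passed in edgeR over all listed tRFs and 20 adjusted over the list alone. Every listed tRF passed that test, so this was fixed by the listing and says nothing about these tRNAs. In the direction test Lys-TTT passed (adjusted p = 0.0369, Fisher's exact test), as did His-GTG with the value given for tRNA-His.

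Of the 112 listed tRFs, 72 matched more than 1 tRNA gene and up to 41, so their reads could not be assigned to 1 locus. Among those that could, Arg-CCG-2 is encoded on chromosome 17 from 23550263 to 23550335 and Pro-TGG-1 on chromosome 7 from 98815415 to 98815486 (GRCm38.p6), in neither case inside a gene of the GENCODE annotation. The Arg-CCG-1 and Arg-TCG-2 genes that share the 42 to 73 fragment lie on chromosome 13 from 21215458 to 21215530 and on chromosome 11 from 115413779 to 115413851, again outside annotated genes. The mitochondrial genome gave 2 listed tRFs, both internal and both listed up. One came from mt-Tm, the mitochondrial methionine tRNA gene (chromosome M, 3861 to 3896, plus strand), with a log2 fold change of 2.85, and the other from mt-Tp, the mitochondrial proline tRNA gene (chromosome M, 15366 to 15404, minus strand), with one of 2.76. These 2 were named after their values were seen, since a count this small falls outside the rule for named tRFs.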

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

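Groups of 4 libraries were examined for a library whose gap to its nearest neighbour took most of the group's range (Dixon's criterion), over the CPM of the named tRFs, the group sums, the library sizes and the listed totals. Of 96 such groups 13 held one, where chance gives about 1 in 20, or 4.8. The quantities overlap, so the 13 are not independent.

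Among named tRFs with reads in all 4 libraries of the group, the tRNA-His 21 to 53 fragment stood at 543 CPM in control replicate 1 against 171 to 231 CPM in the other controls, the Arg-CCG-1 and Arg-TCG-2 42 to 73 fragment at 21.5 CPM in control replicate 3 against 2.53 to 4.55 CPM (2 or 3 reads each), and the Pro-TGG-2 1 to 38 fragment at 461 CPM in cytokine replicate 3 against 120 to 170 CPM in the other cytokine libraries. The Pro 1 to 31 fragment stood at 1660 CPM in cytokine replicate 4 against 1160 to 1240 CPM, and the Arg-TCG-3 28 to 76 fragment at 182 CPM in cytokine replicate 3 against 122 to 130 CPM.

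Among sums, the 5-tRF sum was 134 CPM in control replicate 3 against 236 to 251 CPM in the other controls. The tRNA-Arg sum was 1287 CPM in cytokine replicate 2 against 1758 to 1806 CPM, and within it the Arg-TCG sum was 921 CPM against 1355 to 1379 CPM. The sum of all tRFs listed down was 16857 CPM in control replicate 4 against 12144 to 12824 CPM.

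The remaining 4 were single libraries with reads among libraries with 0: Lys-TTT-1 21 to 70 at 1.501 CPM in control replicate 1, Arg-TCG-4 15 to 54 and His-GTG-2 4 to 30 each at 1.06 CPM in cytokine replicate 4, and the Arg-TCG 28 to 55 fragment at 2.15 CPM in cytokine replicate 2. Each stands for 1 read.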

How the results depend on the processing

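The alternatives were planned except the sizes from the authors' DESeq size factors, chosen after seeing the data. All 112 listed tRFs passed, 29 up and 83 down, with DESeq2, limma, edgeR's exact test, the 2-fold threshold, those DESeq sizes and each library left out (112 to 112); listed totals gave 111 (29 and 82). Listed totals, TMM factors, DESeq2 factors over the listed tRFs and the authors' DESeq factors moved the median log2 fold change by 0.62, 1.84, 1.95 and 0.11. TMM factors left 40 tRFs (29 up, 11 down) and DESeq2 factors 34 (29 up, 5 down), since both set the typical listed tRF to no change and most were listed down. Demanding 10 reads in 4 libraries left 80, of which 15 up and 65 down, because fewer tRFs were tested. Counting each set of parent tRNAs and class once in each direction left 48 of the authors' 112 (14 up, 34 down), and an authors' FDR under 0.005 left 39 (11 up, 28 down). Of the 19 sums 14 passed; 0 did with TMM factors (7 at an unadjusted p under 0.05, all higher and not all among the 14), and leaving out 1 library gave 12 to 14, not always the same sums. The sum of internal fragments and the nuclear sum lost the call without each control, and the Pro-CGG sum without each cytokine library. With 1 library fewer, assignments other than the real one gave differences at least as large. Control and cytokine values did not overlap in any of these sums, so the lost calls do not show that a single library carried the difference. The mean of log2(CPM + 1) gave 15 sums, but that of internal fragments was then 0.19 (adjusted p = 0.509). Of the 10 groups tied to direction, 1 stayed past the threshold when each set of parents and class counted once in each direction, internal fragments, and 6 with the stricter FDR. Counted once per set of parents, class and direction, tRNA-His and His-GTG had 25% of their sets listed up, against 75% of fragments, because the 9 fragments listed up share 1 set and class and the 3 listed down do not.

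The replicate number as a block left 112 tRFs and all 25 named tRFs past the threshold and 0 sums (0 at an unadjusted p under 0.05), since 4 paired differences cannot give a p under 0.125. Same-numbered libraries deviated with correlations of -0.293, 0.172, 0.0953 and 0.0972, and the others with correlations from -0.280 to 0.237. These values show no pairing by number but are too few to exclude one.

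Differences of sums (log2) that changed sign were, with TMM factors, nuclear 1.18, Cys and Cys-GCA 0.15, Pro 0.78, Arg-TCG 0.0647, Pro-CGG 0.25, Pro-TGG 0.60, under 25 nt 0.0225 and 30 nt or more 1.36; with listed totals, 30 nt or more 0.16; with the mean of log2(CPM + 1), 5-tRFs -1.96 and Pro-TGG 0.27; and with 1 library left out, 5-tRFs, which ran from -0.296 to 0.344, and Lys, which ran from -0.134 to 0.336. In the 5-tRF sum the 1 fragment listed up took 226 of 255 CPM with cytokines, while the mean of log2(CPM + 1) weighs it like each of the 5 listed down. The cause was otherwise not tested beyond the scaling itself. Under listed totals, the authors' DESeq factors, the block, DESeq2 and each library left out, 299 values of named tRFs kept direction and call and 1 lost its call (Cys 34 to 53 with listed totals). With TMM and DESeq2 factors all 12 named up passed, but 7 and 3 of the 13 named down, and the report gives those whose sign turned. Depth limits the rare tRFs most: 4 listed up and 8 listed down had under 40 reads over the 8 libraries.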

Other observations

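The tests in this part were chosen after the values were seen. Listed tRFs with some 3′ ends were mostly listed in 1 direction. Of those ending at position 52, 10 were listed up and 0 down, and of those ending at position 54, 1 was listed up and 20 down. At position 53, 4 were listed up and 3 down. Positions are counted within each tRNA, and the last is 75 in nuclear tRNA-Pro and tRNA-His but 76 in tRNA-Arg. The same number can thus stand for different bases in different tRNAs. These counts pool all tRNAs and give no order of 3′ ends between them. All 49 fragments that ended in the full CCA tail were listed down (median log2 fold change -2.33), 47 of them from tRNA-Arg, 1 from Asp-GTC and 1 from Lys-CTT, and the 5 that stopped at the last base before CCA, from tRNA-Arg, tRNA-Phe and tRNA-His, were listed up. Summed over the list, tRFs listed up took 1133, 422, 532 and 688 CPM in control replicates 1 to 4 and 4090, 3309, 8526 and 8265 CPM in cytokine replicates 1 to 4.

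Fragments of the same parent genes with the same start but ends 2 or 3 nt apart were listed in opposite directions in 5 pairs, in all 5 with the shorter one up, though the longer one of the pair Arg-CCG-1 and Arg-TCG-2 39 to 73 and 39 to 76 was above 0 with TMM (0.18) and DESeq2 factors (0.26). In Arg-CCG-2 the fragment of positions 42 to 73 rose by 3.92 on the log2 scale while that of positions 42 to 76 (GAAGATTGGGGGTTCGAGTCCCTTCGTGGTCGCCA) fell by 2.63, and in Pro-CGG-1 positions 18 to 52 rose by 2.57 while positions 18 to 54 fell by 2.69. The log2 ratio of shorter to longer fragment within a library (0.5 reads added) does not depend on library size, and its shift was 4.04 in the smallest and 6.61 in the largest case. The pairs were picked because their fragments were listed in opposite directions, so the size of the shift is no independent evidence that the pattern holds. A factor of the whole library leaves this ratio as it was, so library size alone does not give a shift of 4.04 or more. The same holds for the amount of the parent tRNA in the pairs from 1 isodecoder, where the shifts were 5.12 or more. The pair of Arg-CCG-1 and Arg-TCG-2 (4.04) pools reads of different tRNAs. A change in their relative amounts stays open for that pair. Trimming of 3′ ends stays open as a candidate explanation, at every tRNA or at some, as does a difference between groups in the RNA pretreatment. Pairs of tRNA-His fragments that ended 1 or 2 nt apart shifted by a median of 0.13 (5 pairs, -0.12 to 0.34) and Arg-CCG-2 49 to 74 and 49 to 76 by 0.34. The Lys-TTT-1 pair had 1 and 0 control reads, too few for a ratio. In 4 Arg pairs ending at 54 and 76 the shifts ran from -0.88 to -0.27. Both fragments of each of these pairs were listed in 1 direction, so the shifts cannot decide it.

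In tRNA-His-GTG, 8 internal fragments with starts at positions 17 to 21 were listed up and 3 fragments with starts at positions 0 and 4 were listed down. The log2 ratio of their summed reads within a library was 2.07 ± 1.09 in controls and 7.94 ± 0.93 with cytokines (SD, n = 4 per group), a shift of 5.86. The fragments were grouped after their directions were known, so this value is no independent evidence of the pattern. A factor of the whole library leaves the ratio as it was, so library size alone does not give this shift (5.86). The fragments listed up match His-GTG-2 and His-GTG-3 (9 genes) and those listed down His-GTG-2 only (8 genes), so a change in the amounts of these parent tRNAs stays open, as does a difference in library preparation between the groups, since the labels name no batch.

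Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, called all 112 listed tRFs, and the highest of the others called 0. This says nothing about chance, because the tRFs were listed on the real split.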
